A study of Mus musculus with 229 samples.

How the data were processed

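The series holds single-cell RNA sequencing of mouse cortex and tumour cells by Drop-seq, C1 capture and 10x, and ATAC-seq, which maps open chromatin. The 229 samples were put into 10 groups by assay, strain and stage as their titles give them. Some labels disagree with the titles: the C1 cells of PDGFRa-GFP carry the other strain in a strain field, and the stage and genotype fields of the ATAC samples differ from their titles. The titles were followed. Animals are not named in the labels, so the number of mice per group is unknown. The labels give 2000 cells for the hGFAP-GFP library and 6796 for dpi 25, while the deposited tables hold 815 and 4955, and the rule that removed the others is not stated. The labels do not expand dpi. Per the labels, cortex cells were sorted for GFP and against 7-AAD, a dye of dead cells, while for the tumours a digestion with red blood cell lysis and no sort is given.

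For the 3 Drop-seq libraries, the authors deposited a scaled signal: UMI counts per gene scaled to 10000 per cell, aligned with STAR per the submitters' processing notes. Every value of a cell was a multiple of 1 step, so the UMI counts were recovered by division. In 100% of cells at least 99% of values were whole within 0.1. For the 10x library the deposited values are whole UMI counts from Cell Ranger, per the submitters' processing notes. For the C1 cells the authors deposited TPM values made with RSEM, per the submitters' processing notes. The PDGFRa-GFP table has 46523 gene rows, and its TPM values were rescaled by 1 factor per cell. The hGFAP-GFP table has 24279 gene rows, and 23305 rows are in both. The authors deposited 1 pooled ATAC peak list with a fold ratio of signal over background and -log10 p and q values. The submitters' processing notes name CASAVA, Bowtie2, HOMER and MACS2 2.12, and the builds mm10 and rn5. The intervals lie on mouse chromosomes, and their excess at gene ends was taken as evidence of mm10 coordinates. The list has 93170 summits in 76321 intervals. No read counts of the C1 cells were used here, so their depth is unknown.

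Each droplet library was clustered by itself. Cells with at least 200 genes were scaled to 10000 and log-transformed. The 2000 most variable genes and 30 principal components gave a graph of 15 neighbours, which was split by the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1, with seed 20. A cluster took the class with the most of its markers among the 50 leading genes. The class needed at least 3 there and at least as many as any other class among the first 10. In a cluster of very low UMI number it also needed a marker among the first 10. The classes are called -like, since only markers name them. The marker lists were fixed before the data were examined, as were the gene lists, the comparisons and the rule for named genes. The scoring rule was settled after the clusters had been seen. So were the merging of committed with myelinating oligodendrocytes, of neuroblasts with neurons, of microglia with macrophages and of pericytes with fibroblasts, and leaving unnamed a cluster with over 50% Scrublet doublets. Scrublet, run in scanpy 1.11.5, called 5, 4, 0 and 124 doublets in the PDGFRa-GFP, hGFAP-GFP, dpi 25 and dpi 35 libraries. Shares of classes depend on the gate of the sort.

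Libraries and matched classes were compared as ratios of CPM from summed UMIs, with exact conditional 95% intervals, and a count of 0 was replaced by a floor of 3 UMIs for bounds. Shares have Clopper-Pearson intervals. Both cover counting error only, not differences between animals. Genes named in a contrast are the 12 largest and 12 smallest ratios among those with at least 100 UMIs and 50 CPM in the higher library, leaving out predicted, mitochondrial, ribosomal protein, haemoglobin and sex-linked RNA genes. Members of the fixed lists are named as well. There were 19 marker lists and 14 other gene lists. A list is given by the median of its members with at least 20 summed UMIs, with an exact sign-test interval over members, which spans the whole range for lists of fewer than 6 and covers less than 95% there. Its percentile is among 10000 random lists matched in 20 bins of expression, and describes these libraries only. Shares of cells with a UMI were read after drawing 1000 UMIs from each cell that had as many.

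C1 sets were compared by means over cells, as log2 ratios with a pseudocount of 1, for genes with a mean of at least 1 in either set. A cell was counted for a gene at 10 TPM. The planned test of strain was not made, because the tables were normalized separately. ATAC intervals were compared with 21883 protein-coding gene spans of mm10. The spans have no strand, so the distance was taken to either end and not to a transcription start, with 100 random placements of the intervals. The 200 strain genes each way were compared with random genes of matched expression, in place of the planned permutation test, which needed starts.

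The intervals were tested on simulated counts with counting error only. The 95% interval covered the true ratio for 95.5% of 9548 unchanged genes and for 90.0% to 98.0% of genes changed 1.25- to 4-fold, 50 for each fold. All 200 simulated cells were recovered in full. Alternatives covered resolution, number of variable genes and components, gene minimum, doublets, scaling, thinning, pseudocount, filters and peak thresholds. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9. Gene rows whose names read as dates, 27 in the hGFAP-GFP table with 0.211% of UMIs and 25 in the dpi 25 table with 0.252%, counted toward totals but were never named. Barcode files that repeat the columns of the Drop-seq tables were not used.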

Results

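Single-cell RNA sequencing was done on cells of the mouse cerebral cortex and of mouse tumours labelled GBM, and open chromatin was profiled in PDGFRa-GFP cells. The 229 samples formed 10 groups. Cortex cells came from a pair of reporter strains. In PDGFRa-GFP mice, GFP marks cells that use the promoter of Pdgfra, a growth factor receptor of oligodendrocyte precursor cells (OPCs). In hGFAP-GFP mice, GFP follows a human GFAP promoter that is active in astrocytes and neural progenitors. Each strain had 1 Drop-seq library, from postnatal days 1 to 3 for PDGFRa-GFP and days 5 to 6 for hGFAP-GFP. Each strain also had 2 sets of single cells captured on the C1 chip, with 53 PDGFRa-GFP cells at P6 and 60 at P3, and 49 hGFAP-GFP cells at P3 and 61 at P4 and P6. The tumours gave 1 Drop-seq library at dpi 25 and 1 10x library at dpi 35. Chromatin came from PDGFRa-GFP cells titled E14.5 and P5, which shared 1 pooled peak list.

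The PDGFRa-GFP Drop-seq library held 3184 cells and 8166699 UMIs, with a median of 2014 UMIs per cell. The hGFAP-GFP library held 815 cells and 4196024 UMIs, with a median of 4167. The dpi 25 tumour library held 4955 cells and 11544233 UMIs, with a median of 2063. The dpi 35 library held 6054 cells and 51194749 UMIs, with a median of 6582. No droplet group had a replicate, so values are given without tests. Intervals are exact 95% intervals that cover counting error only. The C1 cells had medians of 5591 and 4124 detected genes in the PDGFRa-GFP sets at P6 and P3, and of 3768 and 3405 in the hGFAP-GFP sets at P3 and at P4 and P6.

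The cortex libraries addressed which progenitor and differentiated cells each reporter captured. Oligodendrocyte-lineage clusters held 34.9% of PDGFRa-GFP and 22.8% of hGFAP-GFP cells, in both libraries more than the astrocyte-like share at the main setting. For hGFAP-GFP this order turned at a Leiden resolution of 0.5, with 17.8% oligodendrocyte-lineage and 19.9% astrocyte-like cells. Astrocyte-like cells were a large class in the hGFAP-GFP library alone. OPC-like cells made up 23.3% of PDGFRa-GFP cells (742 cells, interval 21.8 to 24.8) and no named cluster of the hGFAP-GFP library. Astrocyte-like cells were 1.19% of PDGFRa-GFP cells and 15.2% of hGFAP-GFP cells (interval 12.8 to 17.9). Cells with markers of the primitive OPC, an early glial intermediate progenitor that expresses Egfr and Dll3, were present in similar shares. They made up 10.4% of the PDGFRa-GFP cells (330 cells, interval 9.33 to 11.5) and 9.94% of the hGFAP-GFP cells (81 cells, interval 7.97 to 12.2). Neuronal-like cells were the largest class of the PDGFRa-GFP library at 31.3% (996 cells, interval 29.7 to 32.9) and the largest named class of the hGFAP-GFP library at 24.5% (200 cells, interval 21.6 to 27.6). Cycling clusters held 22.4% of PDGFRa-GFP cells and 5.03% of hGFAP-GFP cells, and 22.3% and 18.2% at a Leiden resolution of 0.5. At 1000 UMIs per cell, Mki67 was found in 15.8% of PDGFRa-GFP and 17.4% of hGFAP-GFP cells (median depths 2014 and 4167). Another 30.7% of hGFAP-GFP cells lay in clusters that met no marker rule, and the largest of these were led by histone genes and by Mcm genes of DNA replication. Oligodendrocyte-like cells, which include newly formed ones, were 1.19% of PDGFRa-GFP and 12.9% of hGFAP-GFP cells. The 105 hGFAP-GFP cells formed 1 cluster with 6 oligodendrocyte and 5 OPC markers among its 50 leading genes, a difference of 1 marker. Both libraries were sorted for GFP and against dead cells, strain and age changed together, and the hGFAP-GFP cells were deeper.

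**Figure D1:**
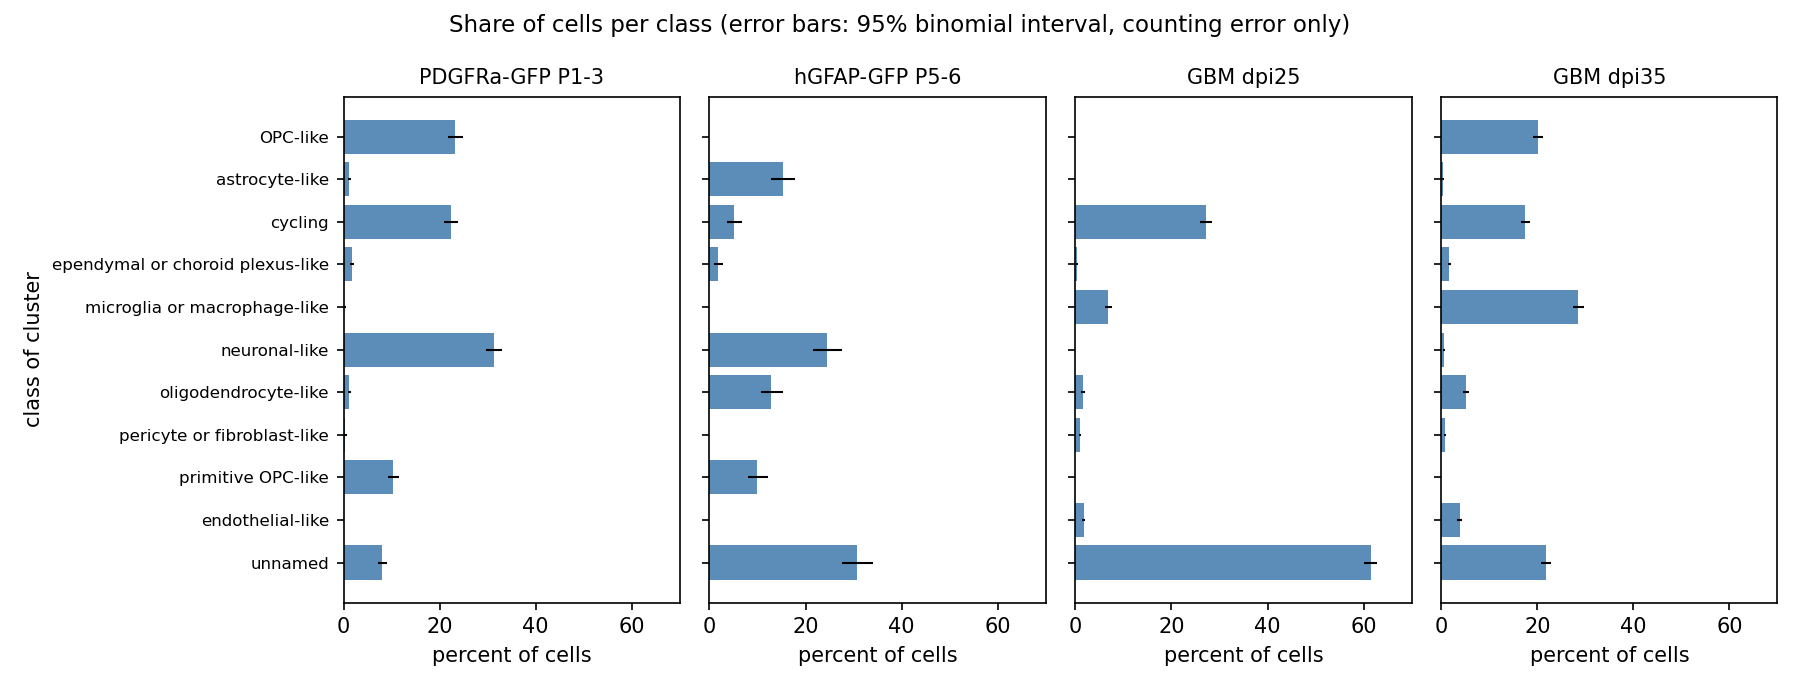
Percent of cells (horizontal axes) in each class of clusters (vertical axis) for the 4 droplet libraries, with 95% binomial intervals as error bars. OPC-like cells reach 23.3% in the PDGFRa-GFP library, astrocyte-like cells 15.2% in the hGFAP-GFP library, and microglia- or macrophage-like cells 28.5% at dpi 35.

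Pdgfra RNA itself was read at a fixed depth of 1000 UMIs per cell. A Pdgfra UMI was found in 32.5% of OPC-like cells of the PDGFRa-GFP library (interval 28.9 to 36.3, median depth before thinning 2263 UMIs). It was found in 13.9% of the primitive OPC-like cells (median depth 1726). In neuronal-like cells the share was 1.67% (interval 0.892 to 2.84, median depth 1434), and in ependymal- or choroid plexus-like cells 1.92% (1 of 52 cells, interval 0.0487 to 10.3, median depth 4703). In the hGFAP-GFP library the oligodendrocyte-like cells had the gene in 40.0% of cells (median depth 4363) and the neuronal-like cells in 1.5% (median depth 3042). Egfr, the receptor of epidermal growth factor, was found in 8.73% of primitive OPC-like cells of the PDGFRa-GFP library and in 11.1% of those of the hGFAP-GFP library. In the hGFAP-GFP library Egfr was not particular to this class, with 11.3% of astrocyte-like cells (median depth 3998) and 12.2% of cycling cells (5 of 41, median depth 7335). The oligodendrocyte-like cells of that library had it in 3.81%. In the PDGFRa-GFP library Egfr was found in 3.13% of astrocyte-like cells (1 of 32), 2.32% of cycling cells and 0.128% of neuronal-like cells.

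Summed over whole libraries, PDGFRa-GFP cells carried more RNA of the oligodendrocyte lineage, and hGFAP-GFP cells more RNA of astrocytes. Of 13 measured OPC markers, 11 were higher in PDGFRa-GFP, with a median log2 ratio of 0.66 (interval 0.11 to 0.86). Olig1, an OPC transcription factor, had 791.1 CPM, its UMIs scaled to the library total, against 323.6, and Pdgfra had 140.7 against 88.4. All 8 measured markers of myelinating oligodendrocytes were higher, at a median of 1.06, among them Mbp, a myelin protein, at 152 against 38.9 CPM (log2 ratio 1.97, interval 1.74 to 2.22). Neuronal lists went both ways: 11 of 14 neuron markers were higher (median 0.70, interval -2.55 to 1.40), and 7 of 11 neuroblast markers (median 0.54, interval -5.20 to 1.04). Gad1 and Dlx5, genes of GABA-producing interneurons, were higher by log2 ratios of 1.88 and 1.75. Of 17 astrocyte markers, 16 were lower in PDGFRa-GFP, with a median of -2.42 (interval -3.15 to -1.73). The water channel Aqp4 had 14.8 against 236 CPM (log2 ratio -3.99) and the glutamate transporter Slc1a2 62.9 against 558. Dio2, which activates thyroid hormone, was lower by a log2 ratio of -3.69. Neurod1 and Eomes, transcription factors of excitatory neuron precursors, had 3.06 against 326 CPM (log2 ratio -6.73) and 3.67 against 135 CPM (log2 ratio -5.20). Among 10000 random lists of matched expression from these libraries, the OPC list stood at the percentile 100 and the astrocyte list at 0.

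Of the 14 measured genes of the Notch pathway 10 were lower in PDGFRa-GFP (median -0.61), while its target Hes5 was higher (326 against 110.6 CPM). Of 13 radial glia markers 10 were lower (median -0.77). Of 17 genes of S phase 16 were higher (median 0.43). All 3 members of the Zfp36 family, proteins that bind RNA and speed its decay, were lower, with Zfp36l1 at 159.8 against 301.2 CPM (log2 ratio -0.91, interval -1.03 to -0.80), and the interval of Zfp36 itself spanned 0. The transcript with the largest difference was Ttr of the choroid plexus, with 81794 UMIs against none, at least a log2 ratio of 13.77 at a floor of 3 UMIs. Ttr stood at 637.7 CPM in the primitive OPC-like and 780.6 CPM in the neuronal-like cells of the PDGFRa-GFP library, and all 5 measured erythroid genes were also higher there (median 7.32). Without clusters named neuronal, immune, vascular, ependymal or choroid the bound for Ttr went to 9.05. The log2 ratio of Ptgds, a prostaglandin synthase, went from 3.91 to 1.16, and the microglia list from a median of 2.38 to -0.89. In this setting a gene with a count of 0 on both sides was set to 3 UMIs on both. Its ratio is then that of the library totals, so the negative median may show no change in expression. Thinning to 1000 UMIs per cell brought the log2 ratio of Mbp to 1.30.

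Within matched classes the strains also differed. In primitive OPC-like cells, 10 of 12 OPC markers were higher in PDGFRa-GFP (median 0.94) and all 14 measured astrocyte markers were lower (median -2.87). Sox10, a factor of the oligodendrocyte lineage, had 164.8 against 25.3 CPM (log2 ratio 2.70, interval 1.81 to 3.75), the Notch ligand Dll3 had 365 against 78.2, and Bcas1, a gene of early oligodendrocytes, 333.9 against 50.6. Slc1a3, a glutamate transporter, had 106 against 722 CPM, and Apoe, a lipid carrier, 264 against 1464. In the neuronal-like class, Neurod1 had 13.7 against 1743 CPM (log2 ratio -6.99), Prox1 had 55.5 against 575, and the serotonin receptor gene Htr3a had 114 against 20.7 (log2 interval 1.71 to 3.33). The hGFAP-GFP class joined a cluster with Gad1 among its leading genes (118 cells) and one with Neurod1 and Neurod2 (82), while 947 of the 996 PDGFRa-GFP cells formed 1 cluster with Gad1. Oligodendrocyte-like cells of PDGFRa-GFP had more myelin RNA, with all 7 myelin markers higher (median 3.66) and Mag at 876 against 28.2 CPM, and they had no Pdgfra UMI against 561 CPM. In astrocyte-like cells 12 of 13 genes of the G2 and M phases had higher summed RNA in PDGFRa-GFP (median 1.45). Without thinning, Mki67 had a UMI in 13.2% of these cells against 13.7% in hGFAP-GFP, and Top2a in 21.1% against 12.9%, at median depths of 1940 and 3998. These classes were small, with 38 oligodendrocyte-like and 38 astrocyte-like cells in the PDGFRa-GFP library, and their names do not make them the same state in both libraries.

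The tables of the C1 sets allowed comparison of stages within a strain. In PDGFRa-GFP cells, oligodendrocyte-lineage genes were higher at P6 than at P3, and neuroblast and cell cycle genes lower. All 14 OPC markers were higher at P6 (median log2 ratio 1.33, interval 0.60 to 2.04), as were all 11 markers of committed oligodendrocytes (median 1.26). Pdgfra averaged 151.8 TPM, transcripts scaled to the total of a cell, at P6 and 37.7 at P3, and reached 10 TPM in 50.9% and 18.3% of cells. Sox10 averaged 106 and 24.1 TPM and reached that level in 62.3% and 16.7% of cells. Of 10 neuroblast markers 9 were lower at P6 (median -1.64), such as the microtubule protein Dcx, at 135.7 TPM against 398, and the interneuron factor Dlx1, at 32.4 against 152.5. All 12 cycling markers were lower (median -1.27), and 17 of 19 genes of the G2 and M phases (median -1.33). All 3 genes of the Zfp36 family were higher, with Zfp36l1 at 81.7 TPM and 58.5% of cells at P6 against 12.5 TPM and 18.3% at P3. Of 16 genes of cholesterol and lipid synthesis, 15 were higher (median 0.63), at the percentile 91.5 of random lists.

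In hGFAP-GFP cells, markers of radial glia and astrocytes were lower at P4 and P6 than at P3, and neuronal markers higher. All 13 radial glia markers were lower (median -1.55, interval -2.21 to -0.95), with Fabp7, a fatty acid carrier of radial glia, at 3218 against 16879 TPM and the matrix protein Tnc at 135.5 against 391.6. Of 17 astrocyte markers 13 were lower (median -1.09), with Aldoc at 419 against 1731 TPM, and it reached 10 TPM in 21.3% against 63.3% of cells. Gfap averaged 76.4 against 203.7 TPM. All 12 neuron markers were higher (median 2.33, interval 1.73 to 3.86), as were all 10 neuroblast markers (median 1.90), with Stmn2 at 348 against 36.4 TPM and Dcx in 54.1% against 16.3% of cells. The means of 12 of 14 OPC markers were higher (median 0.65, interval 0.26 to 1.72), but cells with at least 3 of these markers were 37.7% against 46.9% (intervals 25.6 to 51.04 and 32.5 to 61.7). Of 12 markers of committed oligodendrocytes 10 had higher means (median 1.17, interval 0.00 to 2.47). Of 8 markers of myelinating oligodendrocytes 7 had lower means (median -0.55, interval -3.38 to 0.97). Of 15 genes of the Notch pathway 13 were lower (median -0.80), and the 3 genes of the Zfp36 family were lower too (median -1.02). Of 19 genes of the G2 and M phases 10 were higher and 9 lower (median 0.02), and cells with at least 3 cycling markers were 50.8% (interval 37.7 to 63.9) against 32.7% (interval 19.9 to 47.5). With the mean over cells of log2(TPM + 1) in place of the log of the mean, the OPC list was at 2.22 in PDGFRa-GFP and 0.17 in hGFAP-GFP, the genes of the G2 and M phases of PDGFRa-GFP at -0.68, and the astrocyte and neuron lists of hGFAP-GFP at -2.15 and 0.85. Each stage was 1 set of cells, so no stage was tested.

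**Figure D2:**
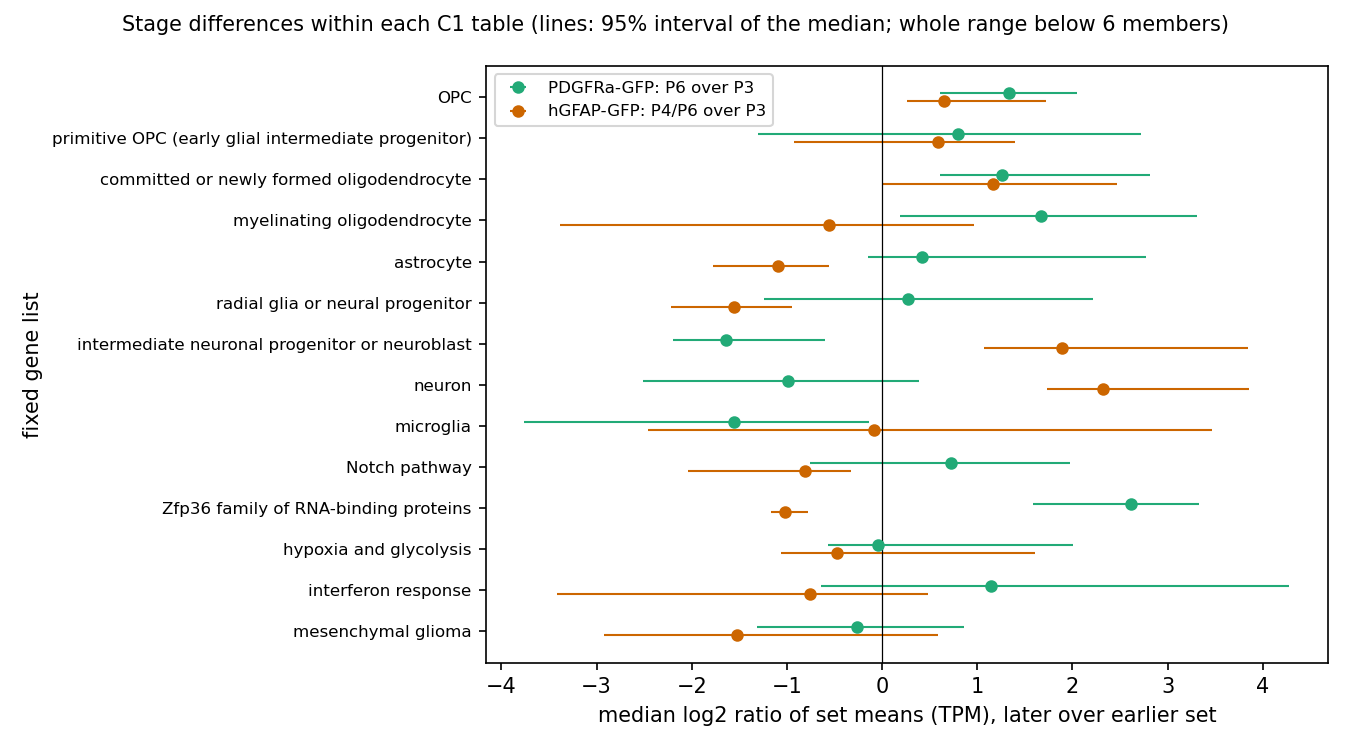
Median log2 ratio of the later over the earlier C1 set (horizontal axis, from means in TPM) for each fixed gene list (vertical axis) in the 2 strains, with 95% intervals over list members as lines (the whole range in lists of fewer than 6). The neuroblast list lies at -1.64 in PDGFRa-GFP and at 1.90 in hGFAP-GFP.

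Across strains the C1 values are set side by side without a test, because the authors normalized the 2 tables separately and over different gene rows. Cells with at least 3 astrocyte markers at 10 TPM were 43.4% and 11.7% of the PDGFRa-GFP sets at P6 and P3, and 73.5% and 34.4% of the hGFAP-GFP sets at P3 and at P4 and P6. Cells with at least 3 neuron markers were 64.2% and 85.0% of the PDGFRa-GFP sets, and 18.4% and 59.02% of the hGFAP-GFP sets. Gfap reached 10 TPM in 1.89% of PDGFRa-GFP cells at P6 and in none of 60 at P3. Neurod1 was listed at 0 in every PDGFRa-GFP cell of both sets and averaged 85.9 and 121.6 TPM in the hGFAP-GFP sets. Egfr reached 10 TPM in 15.1% and 11.7% of the PDGFRa-GFP cells at P6 and P3, and in 38.8% and 19.7% of the hGFAP-GFP cells.

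The tumour library at dpi 25 was set against both cortex libraries, all of Drop-seq, to ask which programmes of glial progenitors the tumours shared. The tumour library had more RNA of Pdgfra and Cspg4, of mesenchymal and hypoxia genes and of interferon response genes, and less of neuronal and Notch genes. Of 13 OPC markers 8 were higher than in PDGFRa-GFP cells (median log2 ratio 0.76, interval -0.92 to 1.16), with Pdgfra at 269.3 against 140.7 CPM (log2 ratio 0.94, interval 0.84 to 1.04) and the proteoglycan gene Cspg4 at 176.5 against 78.7. At 1000 UMIs per cell, 22.9% of the tumour cells had a Pdgfra UMI (median depth 2063), against 2.93% of the microglia- or macrophage-like cells of the same library (median depth 2157). Primitive OPC markers were lower, 8 of 12 (median -1.76), among them Egfr at 2.69 against 23.1 CPM and Dll3 at 27.4 against 114.6. Of 14 Notch pathway genes 12 were lower (median -1.08), and Hes5 had 2.43 against 326 CPM (log2 ratio -7.07, interval -7.66 to -6.54).

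All 15 measured genes of the mesenchymal glioma list were higher than in PDGFRa-GFP cells (median 3.26, interval 2.51 to 5.28), such as the adhesion receptor Cd44 at 90.4 against 2.33 CPM and the filament protein Vim at 1314 against 231. All 16 genes of hypoxia and glycolysis were higher (median 2.43), with Vegfa at 78.2 against 13.8 CPM and Ldha at 907.3 against 140.0. Of 15 interferon response genes 14 were higher (median 3.15), and of 19 genes of the G2 and M phases 17 (median 0.67). Cdkn2a, a tumour suppressor, had 90.95 against 0.49 CPM (log2 ratio 7.54), and Cdkn1a 209.5 against 21.2. Immune and stromal genes were higher as well, with all 12 microglia markers higher (median 3.59), 8 of 9 endothelial markers (median 4.46), Arg1 at a log2 ratio of 10.30 (interval 8.45 to 13.35), Spp1 at 7.51 and Igfbp7 at 7.34. All 14 neuron markers were lower (median -2.76), such as Stmn2 at 6.06 against 1163 CPM, and all 9 neuroblast markers (median -5.52), with Dlx1 at 0.347 against 606. Without clusters named neuronal, immune, vascular, ependymal or choroid, the mesenchymal list stood at 2.40, Arg1 at 5.91 and Igfbp7 at 3.42. The neutrophil list went from 3.82 to -0.72, but genes left at 0 on both sides give only the ratio of library totals.

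Against hGFAP-GFP cells the same library had 15 of 16 mesenchymal genes higher (median 2.91), all 16 hypoxia genes (median 2.01), 18 of 19 genes of the G2 and M phases (median 1.05) and 7 of 13 OPC markers (median 1.45). Of 17 astrocyte markers 15 were lower (median -3.12), with Aqp4 at 7.71 against 236 CPM, and 13 of 14 Notch genes (median -1.83). Spp1, an extracellular phosphoprotein, had a log2 ratio of 13.29 (interval 10.81 to 18.60), and C1qc, a complement gene of microglia, had 3623 UMIs against none, at least a log2 ratio of 8.78. Without the clusters named above these were 7.67 and 3.45. The cortex cells had been sorted for GFP, while no sort is stated for the tumours. In clusters, 27.2% of dpi 25 cells were cycling and 61.5% met no marker rule, or 42.7% and 46.03% at a Leiden resolution of 0.5. The unnamed clusters were led by Cdkn2b, Ccnd2 and Hmga2 (895 cells), by Mcm and Snhg genes (811), by histone genes (565 and 259), by hypoxia genes such as Vegfa and Bnip3 (448) and by interferon genes (70). Oligodendrocyte-like cells of the tumour formed a cluster led by Apod, Klk6 and Mog (39 cells) and one led by Enpp6 (37), while the PDGFRa-GFP class was 1 cluster led by Enpp6. Summed over the class, Apod stood at 20436 CPM against 27.8 in PDGFRa-GFP, and Gpr17, a gene of newly formed oligodendrocytes, at 164.9 against 1419.

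The dpi 35 library could be set against cortex only across platforms. Its OPC-like cells (1216) had all 13 measured mesenchymal genes higher than OPC-like cells of PDGFRa-GFP (median 3.31), 13 of 16 hypoxia genes (median 1.42) and Cdkn2a with 2076 UMIs against none. The median of all genes in this contrast was shifted by -0.31. Microglial C1qb, with 144.8 against 1.08 CPM, was also higher in these cells, and Gfap had a UMI in 22.04% of them at 1000 UMIs per cell (median depth 5482), against 12.3% of microglia- or macrophage-like cells (median depth 6667).

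**Figure D3:**
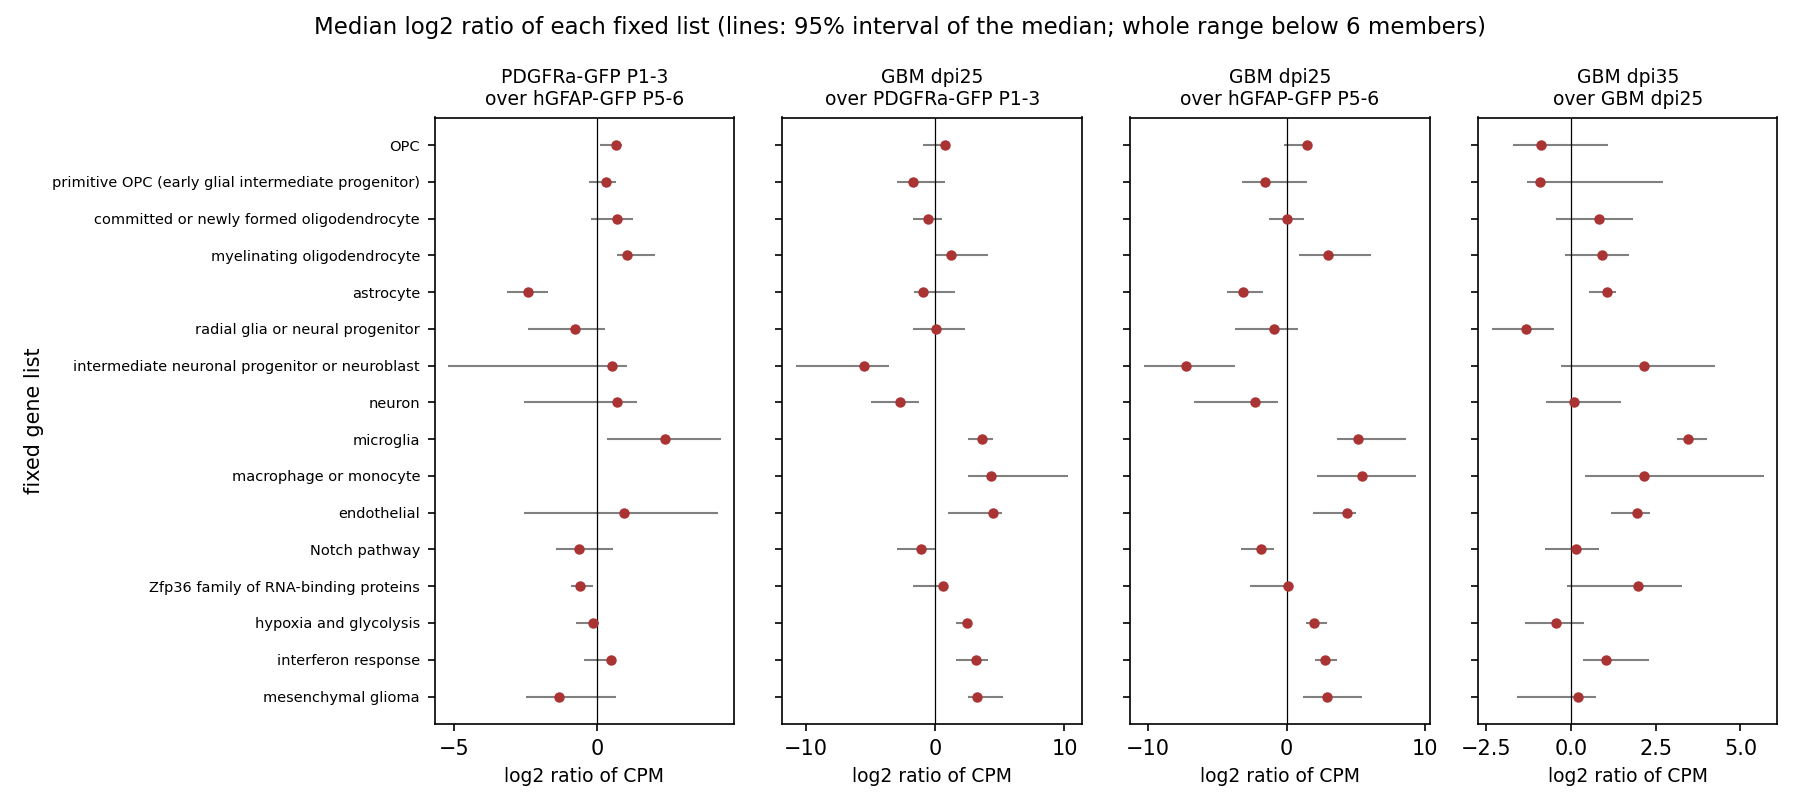
Median log2 ratio of CPM (horizontal axes) of each fixed gene list (vertical axis) for 4 contrasts of whole libraries, with 95% intervals over list members as lines (the whole range in lists of fewer than 6). At dpi 25 the mesenchymal list is at 3.26 over PDGFRa-GFP and at 2.91 over hGFAP-GFP, and the microglia list is at 3.46 in dpi 35 over dpi 25.

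The tumour libraries were then set side by side by time. Immune and vascular genes were higher at dpi 35 and cell cycle genes lower. Microglia- or macrophage-like cells were 28.5% of dpi 35 cells (1727 cells, interval 27.4 to 29.7) and 6.88% of dpi 25 cells (341 cells, interval 6.19 to 7.62). At 1000 UMIs per cell, at least 3 UMIs of the microglia and macrophage marker lists were found in 50.3% of dpi 35 and 7.12% of dpi 25 cells. The background in oligodendrocyte-like cells was 5.45% and 1.32%, so clusters may have missed such cells at dpi 35. OPC-like cells were 20.1% at dpi 35 (interval 19.1 to 21.1) and formed no named cluster at dpi 25. At 1000 UMIs per cell, however, Pdgfra was found in 24.9% of the unnamed dpi 25 cells (median depth 1968), against 22.7% of the OPC-like cells of dpi 35 (median depth 5482). Endothelial-like cells were 3.78% and 1.70%. With 1000 variable genes and 15 principal components, the oligodendrocyte-lineage share of dpi 35 cells went from 25.2% to 11.5%. All 12 microglia markers were higher at dpi 35 (median log2 ratio 3.46, interval 3.13 to 4.01), with the complement gene C1qa at 4173 against 223.1 CPM and Tmem119 at 218 against 11.3. Cd74 and H2-Aa, which present antigen, had log2 ratios of 8.75 (interval 7.71 to 10.06) and 8.46 (interval 6.91 to 10.74). All 10 endothelial markers were higher (median 1.93), such as Cldn5 at 344.8 against 13.9 CPM, and 14 of 17 immediate early and heat shock genes (median 1.32). All 19 genes of the G2 and M phases were lower (median -2.04, interval -2.70 to -1.59), with Mki67 at 94.4 against 466.8 CPM, as were all 17 of S phase. Pdgfra had 74.9 against 269.3 CPM.

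Within microglia- or macrophage-like cells, Cd74 had 881.9 CPM at dpi 35 against 7.04 at dpi 25 (log2 ratio 6.97, interval 5.85 to 8.42), and all 19 genes of the G2 and M phases were lower (median -3.21). Cycling clusters, 27.2% of dpi 25 and 17.4% of dpi 35 cells, were counted apart from this class, so its cell cycle values depend on where cycling cells were grouped. In the same cells 13 of 15 mesenchymal genes were lower at dpi 35 (median -1.72). The class was 1 cluster with Spp1 and Arg1 among its leading genes at dpi 25 and 4 clusters at dpi 35, among them 1 with P2ry12 and Tmem119 (516 cells) and 1 with Chil3, H2-Aa and Cd74 (175 cells). Time changed with platform, Drop-seq at dpi 25 and 10x at dpi 35, and the median of all genes was shifted by -0.28 in whole libraries and by -0.44 in this class. Genes such as Schip1, Taf9 and Dynlt1b were among the lowest ratios, and 8 of 9 mitochondrial transcripts were higher at dpi 35 (median 2.23), although the median mitochondrial share of UMIs per cell was 5.75% against 5.47%. Without clusters named neuronal, immune, vascular, ependymal or choroid the microglia list stood at 6.56, and the log2 ratio of H2-Aa at 4.21, but unnamed dpi 35 clusters stayed in, such as 367 cells led by the macrophage gene Gpnmb.

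Open chromatin of PDGFRa-GFP cells was read from 1 pooled list, which allowed no comparison of ages. It held 76321 intervals on mouse chromosomes with a median width of 230 bp, covering 29.1 Mb. The list includes weak calls: its lowest -log10 q was 0.380, and 19.5% of intervals had a -log10 q above 5. Of the intervals, 63.4% overlapped a protein-coding gene span of mm10 (interval 63.02 to 63.71), against 40.3% of randomly placed ones. A share of 26.6% lay within 1 kb of either end of a span, against 3.63% at random. The Egfr locus on chromosome 11 had the highest interval of the fixed loci, from 16950760 to 16951861, with a fold enrichment of 18.7 at 36.9 kb outside the gene. Id4 and Id2, inhibitors of differentiation, had intervals of 16.2 and 15.7 fold within their spans. Pdgfra had 9 intervals in its span, the highest at 75155683 to 75156499 on chromosome 5 with a fold of 10.1. The nuclear factor genes Nfia, Nfib and Nfix had 69, 28 and 46 intervals in their long spans of 540.8, 216.6 and 96.5 kb. Within 50 kb of these spans, only 8, 6 and 14 intervals had a -log10 q above 5. The highest fold within 50 kb was 4.04 at Aqp4, 4.55 at Nkx2-2, 6.07 at Gfap, 6.57 at Sox6, and 7.58 at Sox10 and at Olig1, whose interval was also the highest near Olig2, at 40.9 kb from its span. Zfp36, Zfp36l1 and Zfp36l2 had highest intervals of 13.1, 8.59 and 12.6 fold, at 13.3 kb, 19.3 kb and 0 kb from their spans. The intervals were not assigned to genes by any test.

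**Figure D4:**
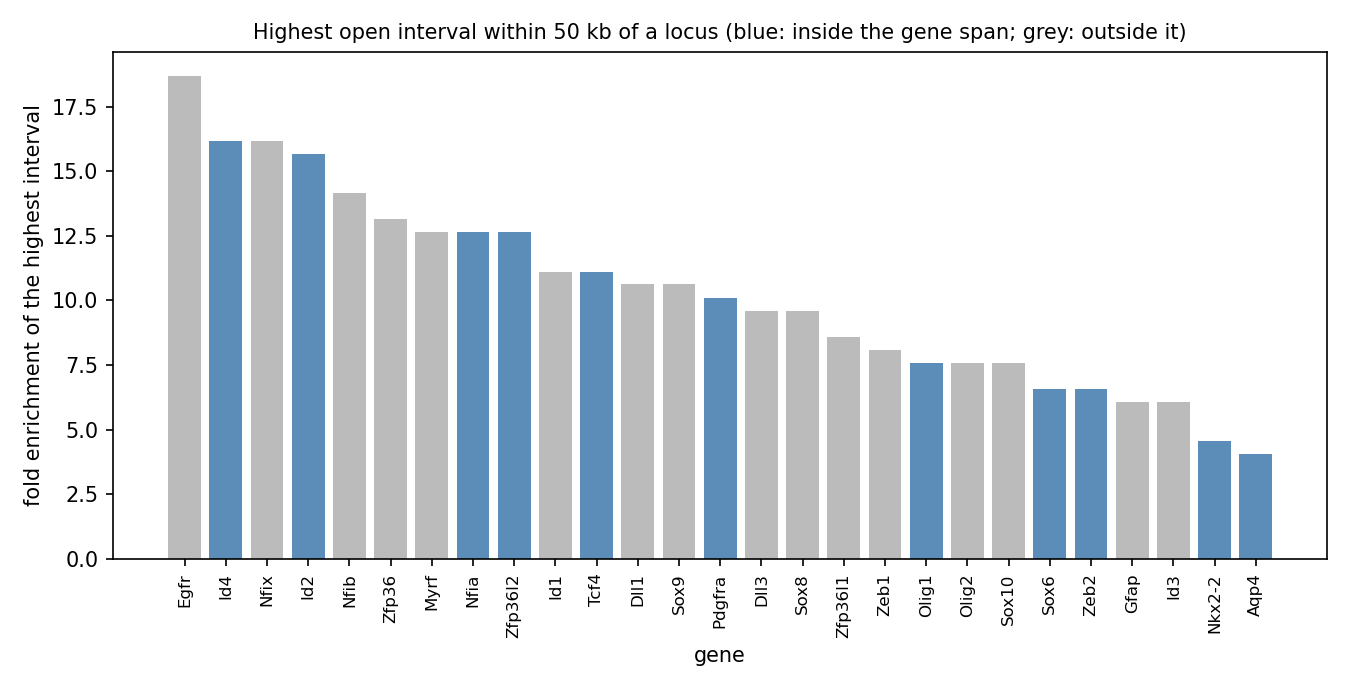
Fold enrichment (vertical axis) of the highest interval within 50 kb of genes fixed beforehand, 1 of them not drawn (horizontal axis), blue inside the gene span and grey outside it. Egfr is highest at 18.7 and Aqp4 lowest at 4.04.

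Intervals at genes that set the strains apart were counted for the 200 genes with the largest C1 ratios each way. An interval lay within 1 kb of a span end for 67.5% of the genes higher in PDGFRa-GFP (interval 60.5 to 73.9) and for 71.0% of those higher in hGFAP-GFP (interval 64.2 to 77.2). Random genes of matched expression had 89.5% for both. The genes came from means that the authors normalized separately in each table, so their choice rests on levels set across tables. Only intervals with -log10 q above 5 gave 41.5% and 38.5%, against 70% and 69% of random genes.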

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

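The test of detected genes in the C1 sets was chosen only after the result was seen.

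Neuroblast markers went opposite ways with stage in the C1 sets of the 2 strains: their median log2 ratio was -1.64 in PDGFRa-GFP, later over earlier, and 1.90 in hGFAP-GFP. The difference between strains was not tested, since each stage is 1 set of cells. If more detected genes per cell had raised the markers, the set with more cells carrying neuron markers should have had the larger number of detected genes. The PDGFRa-GFP set at P3 had 85.0% of such cells but a median of 4124 genes, below the 5591 at P6, and the hGFAP-GFP set at P4 and P6 had 3405 against 3768, which argues against that explanation. A difference in the animals, the dissection or the true course of age stays open and was not tested.

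The Zfp36 family also moved apart with stage, at 2.61 in PDGFRa-GFP (percentile 99.6 of random lists) and -1.02 in hGFAP-GFP (percentile 14.46), and this difference was not tested. In PDGFRa-GFP 11 of 15 immediate early and heat shock genes were higher too (median 0.86, percentile 95.9). Genes of cholesterol and lipid synthesis had medians of 0.63 in PDGFRa-GFP (percentile 91.5) and -0.81 in hGFAP-GFP (percentile 0.56), a difference that was not tested either.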

How the results depend on the processing

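The clustering without cell cycle and histone genes, the contrasts without clusters named neuronal, immune, vascular, ependymal or choroid, all C1 stage alternatives, the C1 shares rescaled to shared rows and the Drop-seq strain genes were chosen after seeing the data; the others were planned. No paired analysis was possible because the labels pair no samples and no group has matched animals. Of the main class shares, 42 values stayed within their counting intervals and 18 moved, and of the other class shares 77 stayed and 37 moved, among them hGFAP-GFP cycling cells to 18.2% and dpi 25 cycling cells to 42.7% at resolution 0.5. The limit of 500 genes per cell removed no cell, since the lowest gene numbers of the libraries were 500, 904, 801 and 647. Leaving out Scrublet doublets removed no dpi 25 cell. These reruns could not move a share but are counted among those that stayed. At Leiden resolution 0.5, hGFAP-GFP astrocyte-like cells were 19.9% and oligodendrocyte-lineage cells 17.8%, the reverse of their main order. At the same resolution dpi 35 immune cells were 30.3% and oligodendrocyte-lineage cells 28.6%. At resolution 2.0, neuronal-like cells were 36.1% of PDGFRa-GFP and 28.3% of hGFAP-GFP cells, hGFAP-GFP oligodendrocyte-lineage cells 17.2%, and dpi 35 immune cells 24.2% and oligodendrocyte-lineage cells 17.2%. With 1000 variable genes and 15 components these dpi 35 shares were 24.7% and 11.5%. Without Scrublet doublets, PDGFRa-GFP neuronal-like cells were 33.6%, and hGFAP-GFP astrocyte-like and oligodendrocyte-lineage cells 18.4% and 19.4%. Without cell cycle and histone genes, the hGFAP-GFP shares were 19.1% astrocyte-like, 36.4% neuronal-like and 30.4% oligodendrocyte-lineage, and the dpi 35 immune share was 29.9%. Of the main list medians between libraries, 52 stayed within their intervals and 3 moved, all without the named non-glial clusters (unnamed ones, such as 367 dpi 35 cells led by Gpnmb, were kept): mesenchymal genes at dpi 25 over PDGFRa-GFP to 2.40, and at dpi 35 over dpi 25 microglia markers to 6.56 and genes of the G2 and M phases to -1.59. Among the other lists 520 stayed, 25 moved and 2 reversed under the same setting, the microglia list in cortex to -0.89 and the neutrophil list at dpi 25 over PDGFRa-GFP to -0.72. Both reversed medians may reflect library totals only, since a count of 0 on both sides was set to 3 UMIs. Of values for single named genes 387 stayed and 93 moved, and none reversed. For the main C1 stage medians 64 values stayed and 6 moved, all with the mean over cells of log2 values: in PDGFRa-GFP the OPC list to 2.22, neuroblasts to -2.39 and G2 and M phases to -0.68, and in hGFAP-GFP OPC to 0.17, astrocytes to -2.15 and neurons to 0.85. Of the other C1 medians 275 stayed and 3 moved, and all 96 C1 shares stayed. A limit of 2000 genes kept 53 of 53 and 60 of 60 PDGFRa-GFP cells at P6 and P3. It kept 48 of 49 and 58 of 61 hGFAP-GFP cells at P3 and at P4 and P6, so it could move little. Intervals with -log10 q above 5 numbered 14890, with 79.97% in gene spans and 58.96% near an end, and within 2.5 kb the share near an end was 36.7%. The strain genes higher in PDGFRa-GFP had intervals for 41.5% (q), 75.5% (2.5 kb) and 84.0% (Drop-seq genes), against 70%, 93% and 92.5% of random genes, and those higher in hGFAP-GFP for 38.5%, 78.0% and 80.5%, against 69%, 92.5% and 92.5%. For the Drop-seq genes higher in PDGFRa-GFP, the mean number of nearby intervals was 11.35 against 11.24 of random genes. For all these moves the cause was not tested, apart from a stricter or wider limit on intervals, which by construction keeps fewer or more of them. For the C1 strain contrast, leaving out sets, the age block, DESeq2, limma without trend, camera and fry, and the pseudocounts and filters were not run, since no strain test could be made. Depth limits the shares of cells with a UMI, and 1 library per group limits every droplet value.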

Other observations

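The test of doublets, and the use of both intervals in the test of Pdgfra, were chosen only after the result was seen, and the other tests were set before it.

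The dpi 35 tumour held several immune and stress states that no comparison described. One unnamed cluster of 367 cells was led by Gpnmb, Igf1 and Cd5l, genes of lipid-handling macrophages, and another of 181 cells by Cst7 and Ftl1. A cluster of 121 cells was led by interferon genes such as Rsad2, Ifit3 and Cxcl10, one of 137 cells by the heat shock genes Hspa1a and Hspa1b, and one of 139 cells by the hypoxia genes Vegfa and Bnip3. A cluster of 269 cells led by the neuronal genes Slc17a7 and Camk2a had a median mitochondrial share of 42.3%. A cluster of 108 cells was 78.7% Scrublet doublets. Ependymal- or choroid plexus-like cells were 99 of the dpi 35 cells, and all 9 of their measured markers were higher than at dpi 25 (median log2 ratio 3.38).

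In the hGFAP-GFP library, an unnamed cluster of 43 cells was led by Naaa, Fam107a, Entpd2 and Veph1. In the PDGFRa-GFP library, 27 cells were set apart by the X-linked genes Xlr3a, Xlr3b and Xlr4a. In the neuronal-like cells of PDGFRa-GFP, 11 of 14 genes of cholesterol and lipid synthesis were higher than in those of hGFAP-GFP (median 0.78). In the C1 PDGFRa-GFP sets, 11 of 14 genes of synapses and ion channels had higher means at P6 (median 1.16).

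Neuronal-like cells formed 31.3% of a library sorted for PDGFRa-GFP. The test at equal depth gave Pdgfra UMIs in 1.67% of them (interval 0.892 to 2.84), far below 32.5% in OPC-like cells. The rule set beforehand compared this share with the 1.92% in ependymal- or choroid plexus-like cells, without intervals. By that rule the values counted for cells with no Pdgfra RNA above background passing the gate. The background rests on 1 of 52 cells (interval 0.0487 to 10.3), too few to tell whether the neuronal-like share lay above it. With the intervals used, the test therefore decides nothing. Doublets of a neuron with a glial cell would carry more UMIs, but the neuronal-like cells had a median of 1434 against 2263 in OPC-like cells, which argues against doublets as the source of the class. Whether they keep GFP protein from an earlier stage or lay near the border of the gate was not tested and stays open.

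Microglia- or macrophage-like cells were 28.5% of the dpi 35 and 6.88% of the dpi 25 library. Thinning each dpi 35 cell to 2063 UMIs, the dpi 25 median, and asking for 801 genes removed 534 cells and left a share of 28.73% of 5520 cells. The gene minimum at equal depth thus left the dpi 35 share much as it was. The classes were those named at full depth, and differences in depth between cells were removed. Whether the lower depth lowered the dpi 25 share therefore cannot be decided from this test. At equal depth, cells with at least 3 UMIs of the marker lists were 7.12% at dpi 25 and 50.3% at dpi 35, against 1.32% and 5.45% of oligodendrocyte-like cells as background, which argues against cells missed by the naming at dpi 25. At dpi 35 the share lay above the named 28.5% by more than that background, so the naming may have left out such cells there. Platform and time changed together, so cell capture by each platform and growth of the immune population cannot be told apart.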
